A study of Mus musculus with 4 samples.

How the data were processed

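Runx1 was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in FDC-P1 cells, a mouse myeloid progenitor line that grows in interleukin-3. One pair of libraries carries the title of FDC-P1 cells with a RUNX1-ERt2 construct, and the other carries the title of FDC-P1 alone. RUNX1-ERt2 is RUNX1 joined to a modified oestrogen receptor domain that responds to hydroxytamoxifen. Each pair holds 1 library made with a rabbit Runx1 antibody and 1 made with rabbit IgG, so there are 4 libraries in 4 groups of 1. Per the labels' protocols, chromatin was fixed with 1% formaldehyde and sonicated to 200 to 500 bp, DNA fragments of 200 to 400 bp were selected, and the RUNX1-ERt2 cells received 1 µM hydroxytamoxifen for 48 h before the assay.

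The labels disagree on which cells each library came from. In all 4 libraries the title and the infection tag name different cells: the pair titled RUNX1-ERt2 is tagged as infected with GFP, and the pair titled FDC-P1 is tagged as infected with RUNX1-ERt2. The source name of each library goes with the infection tag and against the title: it is wild-type FDC-P1 for the pair titled RUNX1-ERt2, and FDC-P1 RUNX1-ERt2 for the pair titled FDC-P1. The titles match the names that link each library to its peak list, so the groups follow the titles, which does not settle which cells were used. The lists are called the RUNX1-ERt2-titled list and the FDC-P1-titled list throughout, and no difference between them is assigned to the presence of the construct or to hydroxytamoxifen.

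The submitters' processing notes name Bowtie 0.12.8, MACS 1.4.1 and the mouse build mm9, with no settings. The threshold for peaks, the treatment of duplicate reads and the number of reads per library are not given in the sources used here, so the sequencing depth is unknown. Each deposited list holds 1 bp intervals with MACS peak names and 1 whole number per interval, with no header. This is the layout of the MACS summit file, in which that number is the pileup signal, the height of overlapping fragments at the summit. The deposited signal values were read in that sense and are called summit heights. Nothing in the values shows that they were scaled to depth. The heights were therefore used only to describe and rank summits within their own list, and a height in one list is not comparable with a height in the other. Positions are given in mm9, counted from 1.

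No genome or annotation of mm9 was used here. The gene table at hand belongs to GRCm38, and 71 summits of the RUNX1-ERt2-titled list and 36 of the FDC-P1-titled list, on 6 chromosomes, lie beyond the last gene of that assembly. Its coordinates were not mixed with those of the lists. Summits are therefore named by position only, and promoter shares, sequence motifs, gene lists and target genes, which had been planned, were not analysed here.

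The planned rule called 2 peaks shared when they overlapped by at least 1 bp. Because the lists hold summits of 1 bp and not intervals, an alternative that had also been listed took its place: a summit was called shared when a summit of the other list lay within 250 bp. Planned comparisons of peak width could not be made for the same reason, and heights were compared instead. Shared percentages carry Wilson 95% intervals. Chance overlap came from 1000 random placements of a list within each chromosome, between the first and the last summit of either list, and from 1000 random shifts of up to 50 kb. Quartiles of height were formed within each list, with ties at a boundary split by file order, and the top and bottom quartiles were compared with Fisher's exact test (two-sided). Mean heights of shared and unshared summits were compared with a permutation test of 100000 resamples (two-sided), whose smallest possible p is 1e-05. Summits are not replicates of a condition, so these tests describe the lists at hand. With 1 antibody library per title no difference between the lists has a replicate check, and none carries a p-value. The Wilson and Poisson intervals cover counting error only.

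One-to-one pairs are summits of the 2 lists that are each other's nearest and lie within 250 bp. Intervals of height ratios between chromosomes came from 2000 bootstrap resamples of the pairs or of the unshared summits and cover the spread of regions only. Groups of neighbouring summits were chained with gaps of at most 10 kb and compared with 200 random placements. The summits named in the text are the 10 tallest in each of 3 classes: shared, ranked in the shorter list, and unshared in either list. The number and the classes were set before the data were examined, for overlapping peaks ranked by the submitters' score; the 250 bp distance and the summit height took the place of the overlap and the score once the files had been seen. The sharing calculation was tested on simulated lists of 3521 summits in which 30%, 60% or 90% were placed near summits of the longer list. Their offsets were normal with an SD of 40 bp, and it returned 30.1%, 60.1% and 90.0%. Such offsets lie well inside 250 bp, so this checks the calculation and not whether the 250 bp rule suits the deposited lists. Alternatives covered the matching distance, the length of the lists, a minimum height and the chromosomes used. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.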

Results

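Runx1, the DNA-binding subunit of core-binding factor and a regulator of blood cell formation, was mapped with an antibody against its C-terminal end in 2 cultures of the FDC-P1 line, each set against its own IgG library. The RUNX1-ERt2-titled list held 6326 summits and the FDC-P1-titled list 3521, a ratio of 1.80. In the RUNX1-ERt2-titled list the summit height had a median of 19 (quartiles 15 and 26, range 7 to 156). In the FDC-P1-titled list the median was 10 (quartiles 8 and 12, range 6 to 91). Read as fragment counts, these medians have exact Poisson 95% intervals of 11.4 to 29.7 and 4.80 to 18.4. They give the counting error of a free count at the median height only. Listed summits had passed a peak threshold, and 4.80 lies below the smallest height in its list. The number of reads behind each library is unknown, so neither the heights nor the numbers of summits measure a difference in binding between the cultures. The libraries had no replicates, and the labels disagree on which list came from the cells with the RUNX1-ERt2 construct.

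The first comparison asked how many positions the 2 lists had in common. Of the 3521 summits in the FDC-P1-titled list, 2346 lay within 250 bp of a summit in the RUNX1-ERt2-titled list, which is 66.6% (Wilson 95% interval 65.1 to 68.2). In the other direction 2334 of 6326 summits were shared, or 36.9% (35.7 to 38.1). The remaining 1175 summits of the FDC-P1-titled list and 3992 of the RUNX1-ERt2-titled list had no such partner. Random placement within chromosomes gave a shared percentage of 0.141% ± 0.0622 (SD of 1000 placements) for the FDC-P1-titled list. Random shifts of up to 50 kb, which keep the regional density of summits, gave 0.912% ± 0.158. None of the 1000 placements or shifts reached the observed value. Neither kind of placement is limited to open chromatin. When both lists were cut to their 1000 tallest summits, 42.6% of either list was shared.

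Paired summits lay close together in the 2 libraries, within a limit of 250 bp set by definition. The 2334 one-to-one pairs were a median of 36 bp apart (quartiles 16 and 66), 90.8% lay within 100 bp and 22 pairs shared the exact base. Within the pairs the heights in the 2 lists were related across regions, with a Pearson r of 0.48 and a Spearman rho of 0.41, each with a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. Regions of one library are not independent replicates.

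**Figure D1:**
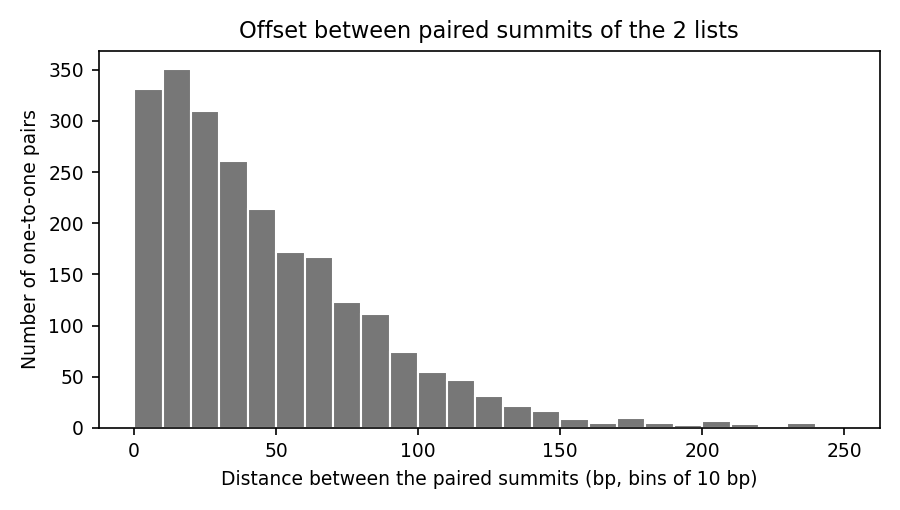
Histogram of the distance in bp (x axis, bins of 10 bp) between the summits of each of the 2334 one-to-one pairs (y axis, number of pairs). The bins up to 30 bp are the fullest, the median is 36 bp, and 90.8% of pairs lie within 100 bp.

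Tall summits were shared far more often than low ones in both lists. In the RUNX1-ERt2-titled list, 14.2% of the lowest height quartile (7 to 15) was shared (12.6 to 16.0), against 69.0% of the highest quartile (26 to 156; 66.7 to 71.2). In the FDC-P1-titled list the shared percentage was 48.4% in the lowest quartile (6 to 8; 45.1 to 51.7) and 88.8% in the highest (12 to 91; 86.5 to 90.7). The difference between top and bottom quartile had a Fisher's exact p of 1.21e-228 in the RUNX1-ERt2-titled list and 1.41e-78 in the FDC-P1-titled list, both two-sided. The mean height of shared summits in the RUNX1-ERt2-titled list was 28.1 ± 13.1 (SD, 2334 summits), against 18.5 ± 7.76 for the 3992 unshared ones. In the FDC-P1-titled list it was 11.3 ± 3.95 (2346 summits) against 9.29 ± 4.85 (1175 summits). Both differences in mean height had a two-sided permutation p of 1e-05, the smallest value possible. The medians of shared and unshared summits were 25 and 16 in the RUNX1-ERt2-titled list, but only 10 and 9 in the FDC-P1-titled list. Unshared summits of the FDC-P1-titled list include heights of 91, 87, 74 and 73, far above that median.

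**Figure D2:**
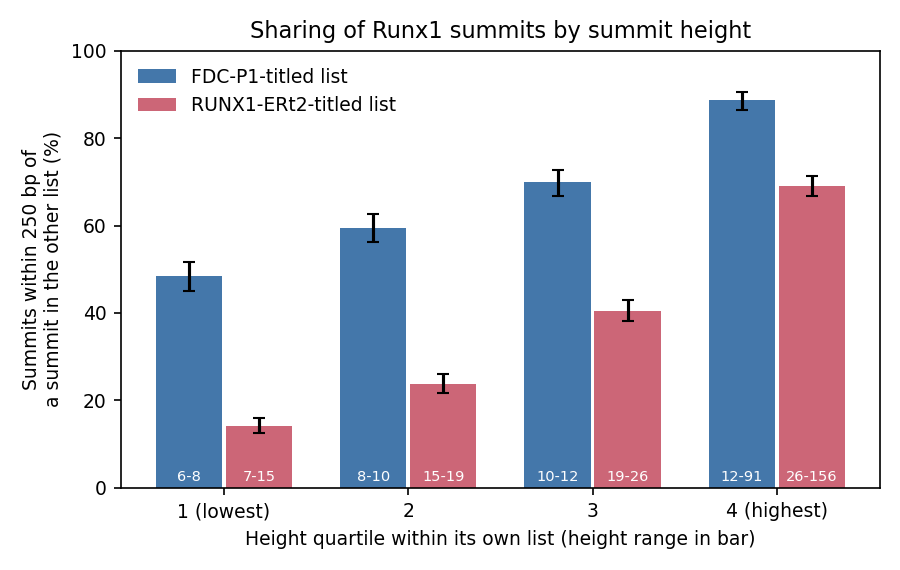
Percentage of summits within 250 bp of a summit in the other list (y axis) by quartile of summit height within its own list (x axis), for both lists. Bars are percentages, error bars are Wilson 95% intervals, and the height range stands at the foot of each bar; the percentage is higher in each successive quartile, from 48.4% to 88.8% in the FDC-P1-titled list and from 14.2% to 69.0% in the RUNX1-ERt2-titled list.

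The tallest shared positions lay on several chromosomes. The summit with the greatest height among the pairs, ranked in the FDC-P1-titled list, was at chromosome 9, position 44689538, with a height of 37 there and of 75 in the RUNX1-ERt2-titled list, at position 44689548. The next was at chromosome 1, position 145313394 (height 35), whose partner at 145313440 had a height of 60. Chromosome 7, position 19663304 followed with a height of 33 and a partner of height 57 at 19663317. At chromosome 12 the summit at 27083623 had a height of 31 and its partner at 27083598 a height of 61. At chromosome 1, position 166065671, both lists placed the summit on the same base, with a height of 30 in the FDC-P1-titled list and of 91 in the RUNX1-ERt2-titled list. The other 5 of the 10 tallest were at chromosome X 98417960, chromosome 1 172466678, chromosome 4 106973161, chromosome 15 7167177 and chromosome 7 151633214. Over these 10 positions the heights were 29 to 37 in the FDC-P1-titled list and 20 to 91 in the RUNX1-ERt2-titled list.

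Tall summits were a minority of those without a partner in the RUNX1-ERt2-titled list. Of its 3992 unshared summits, 490 were in the highest height quartile and 1357 in the lowest. Of the 490, 416 (84.9%) lay more than 5 kb from any summit of the FDC-P1-titled list. So did 3567 of all 3992 unshared summits, so the tall ones were not more remote than the rest. Apart from a position on chromosome 17 described with the next list, the tallest were at chromosome 9 123832957 (height 88), chromosome 7 29908710 (height 75), chromosome 16 18108404 (height 74) and chromosome 19 4462177 (height 68). The nearest summits of the FDC-P1-titled list were 239966, 428338, 51101 and 13540 bp away. The summit at chromosome 12 12503552 (height 66) missed the matching distance narrowly, with a summit of the FDC-P1-titled list 252 bp away. The remaining 4 of the 10 tallest were at chromosome 19 55623404, chromosome 19 18681014, chromosome 4 46627780 and chromosome 15 27447932, with heights of 66, 65, 59 and 58.

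The FDC-P1-titled list had 99 unshared summits in its highest quartile, of which 74 (74.7%) lay more than 5 kb from any summit of the RUNX1-ERt2-titled list. Of all its 1175 unshared summits, 986 did. Both counts include 2 mitochondrial summits, for which the other list has no summit on the same chromosome. Its tallest were at chromosome 17 39982969 (height 91) and 39985643 (height 87), in a stretch where the RUNX1-ERt2-titled list had its own tallest summit, at 39982043 (height 156), 926 bp from the nearer one. It also held 2 summits on the mitochondrial genome, at positions 12391 (height 74) and 1396 (height 73), where the RUNX1-ERt2-titled list held none. Without an mm9 annotation, repeated or multi-copy sequence on the nuclear chromosomes could not be marked. Whether the heights at these positions reflect Runx1 binding was not tested. After these came chromosome 17 36368233 (height 43) and chromosome 8 20020423 (height 27), each over 5 kb from the other list. Of the 10 tallest unshared summits in this list, 5 had a summit of the other list within 1000 bp. These included chromosome 19 31412146 (height 22), 357 bp away, and chromosome 1 184300099 (height 19), 315 bp away.

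Unshared summits lay near summits of the other list more often than chance placement gave. Between 250 bp and 5 kb from a summit of the RUNX1-ERt2-titled list lay 189 of the 1175 unshared summits of the FDC-P1-titled list, or 16.1% (14.1 to 18.3). Shifts of up to 50 kb gave 7.61% on average and at most 10.0%. In the RUNX1-ERt2-titled list the value was 425 of 3992, or 10.6% (9.73 to 11.6), against 5.22% on average and at most 6.39% under the shifts. Each summit was shifted by itself, so the shifts do not keep the grouping of neighbouring summits within a list. The excess cannot be told apart from that grouping. Many of the 189 lay only just beyond the matching distance. In the FDC-P1-titled list 2346 summits had a partner within 250 bp, 2452 within 1000 bp and 2535 within 5 kb. In the RUNX1-ERt2-titled list the counts were 2334, 2438 and 2759, so a smaller part of the 425 lay that close. The shifts were not split by distance.

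Summits also stood in groups within each list. With gaps of at most 10 kb, 31.8% of the summits in the RUNX1-ERt2-titled list had a neighbour, against 5.40% under random placement within chromosomes and at most 6.42% in 200 placements. In the FDC-P1-titled list it was 18.97% against 3.15%, and at most 4.06%. Such placement does not keep the regional density of summits, and shifts of up to 50 kb were not run for the groups. The excess is therefore not separated from uneven density along the chromosomes. The RUNX1-ERt2-titled list had 45 groups of at least 4 summits and the FDC-P1-titled list had 8. The lists differ in length, and groups of this size were not counted in the random placements. The largest group, 7 summits with heights of 14 to 29 on chromosome 13 from 49276901 to 49309127, was in the RUNX1-ERt2-titled list and held 1 shared summit. A group of 6 on chromosome 4, from 47306742 to 47332657, had 4 shared summits and heights up to 55. The largest group of the FDC-P1-titled list, 5 summits on chromosome 15 from 103085868 to 103099592, held 3 shared ones. The groups were chosen after their sizes were seen.

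Apart from the 2 mitochondrial summits of the FDC-P1-titled list, the summits were spread over the 19 autosomes and chromosome X, with 0 on chromosome Y in either list. Chromosome X held 38 summits of the RUNX1-ERt2-titled list, or 0.601% (0.438 to 0.823), and 19 of the FDC-P1-titled list, or 0.540% (0.346 to 0.841). Chromosome 11 held the most in the RUNX1-ERt2-titled list, 498 or 7.87% (7.23 to 8.56), against 6.65% of the FDC-P1-titled list (5.87 to 7.52). Chromosome 1 held the most in the FDC-P1-titled list, 314 or 8.92% (8.02 to 9.90), against 6.47% of the RUNX1-ERt2-titled list (5.89 to 7.10). Chromosome 12 also took a larger part of the FDC-P1-titled list, 5.57% (4.86 to 6.37) against 4.25% (3.78 to 4.78). On chromosomes 13, 14, 16 and 19 the direction was the same but the intervals overlapped: 5.57% (4.86 to 6.37) against 4.87% (4.37 to 5.43), 4.03% (3.43 to 4.73) against 3.71% (3.28 to 4.21), 4.03% (3.43 to 4.73) against 3.57% (3.14 to 4.06) and 5.48% (4.78 to 6.28) against 4.57% (4.08 to 5.11). Chromosome 18 was nearly even, at 2.30% (1.85 to 2.85) against 2.29% (1.95 to 2.69). The number of summits in the FDC-P1-titled list over that in the RUNX1-ERt2-titled list ranged from 0.46 on chromosome 6 to 0.77 on chromosome 1.

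**Figure D3:**
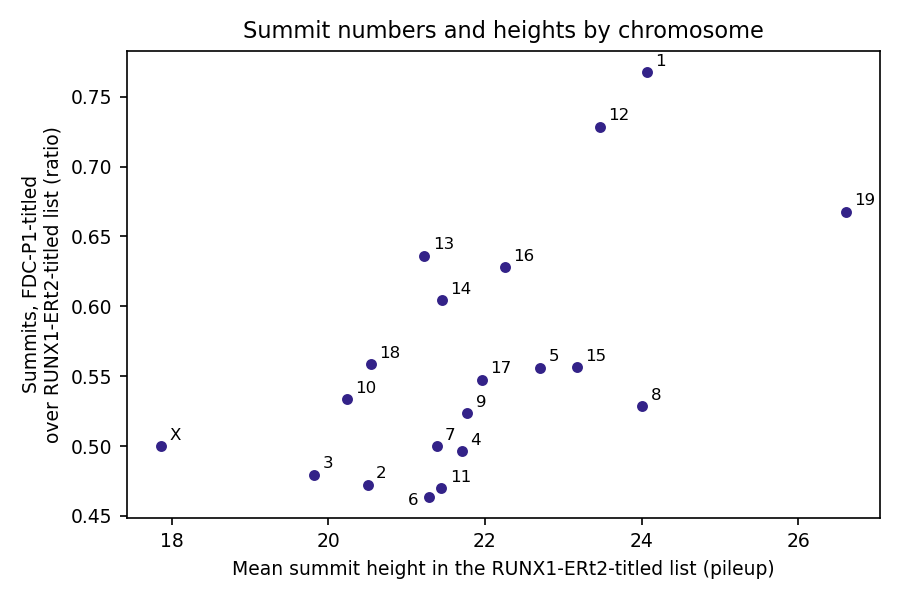
Each point is a chromosome; the x axis is the mean summit height in the RUNX1-ERt2-titled list and the y axis the number of summits in the FDC-P1-titled list divided by that in the RUNX1-ERt2-titled list, with neither axis starting at 0. Chromosomes 1, 12 and 19 have the highest ratios, 0.77, 0.73 and 0.67, at mean heights of 24.1, 23.5 and 26.6.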

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

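The depth of the libraries is unknown, and the median height of 10 in the shorter, FDC-P1-titled list limits what a missing partner shows. The matching distances of 100 and 500 bp, for the quartiles also that of 1000 bp and leaving out the mitochondrial summits, and both cuts of the lists for the parts on chromosomes 1, 12 and 19 were added after the data were examined. A height of at least 100, planned for a p-value score, left 2 summits in the longer list and 0 in the shorter, so sharing under it has no value. The values below give first the shared percentage of the shorter list, then that of the longer list, then the top and bottom quartiles of the shorter list and the top and bottom quartiles of the longer list. Matching at the same base, where overlap by 1 bp and the reciprocal 50% rule coincide, left 22 shared summits, 0.625% and 0.348%, with quartiles of 1.14%, 0.454%, 0.696% and 0.190%, since summits are single bases. Within 100 bp the values were 60.3%, 33.5%, 84.7%, 41.0%, 63.9% and 12.6%. Within 500 bp the shorter list stood at 68.5% and the other 5 percentages stayed inside the intervals reported. Within 1000 bp they were 69.6%, 38.5%, 91.1%, 52.3%, 70.5% (inside its interval) and 16.1%. With the longer list cut to 3521 summits they were 52.3%, 52.0%, 81.1%, 31.2%, 76.0% and 31.2%. With both lists cut to 1000 summits, 426 were shared, 42.6% of either, and quartiles were not computed. Tall summits were shared more often than low ones under each of these that gave quartiles. Shifts of up to 50 kb raised the chance percentage from 0.141% to 0.912%. The part of the longer list on chromosomes 1, 12 and 19 rose from 15.3% to 17.5% with that list cut to 3521 summits; with both cut to 1000 it was 21.8%, and that of the shorter list 27.8%. Leaving out the mitochondrial summits moved no percentage beyond its interval. Of 53 alternatives, 19 stayed within the interval or 1.5 times the count reported and 34 did not. Results on promoters, motifs, widths, genes and gene lists were not run. No replicate could be left out.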

Other observations

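The ratio of summit numbers, FDC-P1-titled over RUNX1-ERt2-titled, varied along the chromosomes. In stretches of 20 Mb with at least 20 summits of the RUNX1-ERt2-titled list, it ran from 0.45 (30 summits over 66) to 1.19 (44 over 37) on chromosome 12, from 0.50 (27 over 54) to 1.19 (25 over 21) on chromosome 1, from 0.36 (35 over 97) to 0.91 (21 over 23) on chromosome 4 and from 0.17 (11 over 63) to 0.68 (32 over 47) on chromosome 6. These chromosomes were chosen after the values were seen, and whether the variation exceeds counting error was not tested.

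The tests of the chromosome pattern, and the use of the planned quartile percentages to test for detection limits, were chosen after the results were seen. The first pattern is that chromosomes 1, 12 and 19, picked because they had the highest ratios, held 19.97% of the FDC-P1-titled list and 15.3% of the RUNX1-ERt2-titled list, with a summit ratio of 0.73 against 0.53 on the other 17; after the longer list was cut to its 3521 tallest summits, the ratios were 1.14 and 0.97. At that equal length chromosomes 1 and 12 stood at 1.23 and 1.17 but chromosome 19 at 0.995, below chromosome 10 (1.11) among others. The excess therefore did not hold on all 3. Chromosome X stood at 1.27, but on only 19 summits of the FDC-P1-titled list. More background summits in the shorter list on these chromosomes stay open: its unshared summits were 1.78 times as frequent per summit of the longer list there and 59.5% of it was shared (Wilson 95% interval 55.8 to 63.0) against 68.5% elsewhere (66.7 to 70.2), while 43.0% of the longer list was shared (39.9 to 46.2) against 35.8% (34.5 to 37.1), and all of these are parts of the ratio that picked the chromosomes. Extra copies of these chromosomes in the cells also stay open: pairs on them were taller by a factor of 1.15 in the RUNX1-ERt2-titled list (bootstrap 95% interval 1.10 to 1.21) and of 1.14 in the FDC-P1-titled list (1.10 to 1.19), and unshared summits by 1.06 (1.02 to 1.10) and 1.04 (0.978 to 1.08). The bootstrap intervals do not cover the picking of the 3 chromosomes. Along chromosome 12 the summit ratio was uneven. In stretches of 20 Mb it was 0.78, 0.80, 0.85 and 1.19 from 0 to 80 Mb, then 0.51 and 0.45 up to 120 Mb. On chromosome 19 it was 0.66, 0.71 and 0.66. Extra copies of a whole chromosome would not by themselves give the fall on chromosome 12, but its counting error was not tested. In the longer list pairs on chromosomes 8 and 15 were as tall (means of 31.9 and 30.4) as those on chromosomes 1 and 12 (30.2 and 30.8). Those on chromosome 19 were taller (34.7). In the shorter list, though, the means on 1, 12 and 19 (12.7, 12.3 and 12.7) lay above those on 8 and 15 (11.5 and 11.4). The tallest summits were concentrated on the 3 chromosomes in both lists: of the 1000 tallest, they held 27.8% in the FDC-P1-titled list and 21.8% in the RUNX1-ERt2-titled list. Denser strong binding and extra copies would both give this, so it does not separate them.

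The second pattern is the set of summits found in only one list. Summits near the detection limit of the libraries may account for part of those found only in the FDC-P1-titled list, whose shared percentage was 1.84 times as high in the top height quartile as in the bottom one (88.8% against 48.4%). For those found only in the RUNX1-ERt2-titled list, sites near the detection limit of the shorter library may likewise account for part: the ratio was 4.85, and 31.0% of the top quartile was still unshared. Both ratios restate the quartile percentages given above. Background summits of low height in either list would also make sharing rise with height, so the ratios do not separate them from sites near the detection limit. How much sharing lower depth alone would leave was not tested, because the depths are unknown. A difference between the 2 cell cultures in Runx1 binding cannot be told apart from a difference between libraries, because there was 1 antibody library per culture and the labels disagree on the cultures.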
